A study of Synechocystis sp. PCC 6803 with 12 samples.

How the data were processed

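The series measured RNA of the cyanobacterium Synechocystis on 12 single-colour Agilent arrays. Per the labels, wild type and a strain with a partially inactivated crhR gene, called crhRTR, were grown at 30 °C, and cultures of both were also kept for 3 h at 20 °C. Each of the 4 groups held 3 arrays, which the labels describe as biological triplicates. Per the labels, total RNA was labelled directly with the dye Cy3 and no cDNA was made, so a probe reads 1 strand. Per the labels, the medium of the mutant also held thiosulphate, tricine and antibiotic, so strain and medium were not separated by the design.

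Per the file headers, the deposited scanner files hold fluorescence intensities from Agilent Feature Extraction 10.5.1.1. Their processed intensity is the background-subtracted signal of each spot with no normalization between arrays, and their raw median intensities of spot and local background are unscaled. Per the file headers, the software's 0 or 1 flags mark spots that are well above background, saturated or outliers. The mean raw intensity was deposited for only some of the arrays. The deposited series matrix holds log2 values: recomputation from the scanner files gave, for every value to within 1e-08, the log2 of the raw median intensity after quantile normalization of the 12 arrays, with no background subtraction. The submitters' processing notes name limma without a version. The main comparisons used the processed intensities, and the deposited log2 values served as an alternative.

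Depth was read as signal over background. Between 66.0% and 84.6% of the probes were well above background per array, the 75th percentile of the processed intensity ran from 2738.6 to 9153.14, and no spot was saturated. The median raw intensity was 1.40 to 2.17 times the median of the array's negative control spots, so many probes lay near the level of those controls. The values of dim features therefore depend on the background subtraction. The number of arrays also limits the precision.

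Of 45220 spots per array, 1417 were controls and were left out, as were the 149 to 203 spots per array with an outlier flag. The log2 processed intensity had the array's 75th percentile subtracted. Spots of a probe were averaged, and then the probes of a feature. A probe was kept if it was well above background on at least 3 of the 12 arrays, which left 17489 of 20644 probes and 5694 of 6015 features. The tested features were 3521 open reading frames, 703 antisense RNAs, 654 internal transcripts, 474 5' UTRs, 298 non-coding RNAs and 44 structural RNAs, by the classes in the deposited names. Where every probe of a feature was dim in all arrays of 1 group, the fold is given as at least the ratio to a bound for that group. The bound takes on each array the higher of the feature's signal and the detection floor, which is the lowest signal of a probe well above background, and averages the arrays in log2.

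The files name open reading frames by locus tag, and other transcripts by class with start and end. The genome build of those positions is not given in the sources used here, so positions are printed only as the deposited names give them. The table of RefSeq genes matched 0 of the 3623 locus tags of open reading frames. Gene symbols therefore came from gene lists written from general knowledge of this organism before the data were examined. No table checked those symbols, so each is printed with its locus tag at first mention. At most a pair of locus tags without a symbol is printed per direction and comparison outside the lists, except for the features whose cold responses differ.

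A fit of 4 group means to all 12 arrays was made with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. Contrasts gave the cold response of wild type, the cold response of crhRTR, the difference between strains at 30 °C and at 20 °C, and the difference of the cold responses. Tests were two-sided, and a feature was called at a Benjamini-Hochberg adjusted p under 0.05 over the 5694 features of 1 contrast. Errors written after ± are standard errors of the log2 difference from this fit, with n = 3 arrays per group, unless SD is written. The overlap of the cold responses was counted per direction against the overlap that independent calls would give.

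The 28 gene lists held 374 entries, of which 373 were on the array, and were tested among open reading frames with camera in limma at its preset correlation of 0.01. The lists were the crhR locus, reported cold-inducible genes, fatty acid desaturases, heat shock and chaperone genes, high-light-inducible proteins, redox and photoprotection, ribosomal proteins, translation factors, photosystem I, photosystem II, phycobilisome, ATP synthase, cytochrome b6f and electron carriers, cytochrome oxidase, the NDH-1 complex, CO2 fixation and carboxysome, inducible inorganic carbon uptake, nitrogen assimilation, iron acquisition and iron stress, the phosphate regulon, tetrapyrrole and chlorophyll synthesis, sugar catabolism, ribonucleases and RNA processing, sigma factors, type IV pili and motility, the circadian clock, and CRISPR-associated genes of plasmid pSYSA. A further list is not reported here, though the counts of called lists are over all 28. Adjustment was over the 28 lists of 1 comparison. The same test with the correlation estimated per list, and fry, were run beside it. The lists share members: desD, for example, is in 2 of them. A check of the members' annotated products was not possible, since no table gave them.

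The design, the lists, the alternatives and the rule for naming genes were chosen before the data were examined. By that rule the text names, per comparison, the 8 open reading frames with the largest rise and the 8 with the largest fall among those called whose 3 arrays of 1 group all lay above or below the 3 of the other, 3 and 3 other features by the same rule, and up to 4 members of a list with the largest absolute change. For the difference of the cold responses it names 6 and 6 open reading frames and 3 and 3 other features. crhR, each of its probes and rimO are named throughout. Only part of the genes the rule allows are printed.

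Alternatives were background correction by normexp with an offset of 50, quantile normalization, both together, median scaling, the deposited values, no filter on dim probes, probes above background on all 12 arrays, the median of the probes, each probe on its own, a fit of 2 groups only, slide as a fixed or random block (statmod 1.5.0), a block of replicate numbers, an intensity trend, an absolute log2 change of at least 1, and leaving out each array. A further pair was added after the data were seen: normexp on raw median intensities of all arrays, since only some files give the mean, and values floored at the highest detection floor. Antisense RNAs and internal transcripts were paired with genes by probe sequences sharing at least 20 bases (Biostrings 2.70.1). The arrays sat on 3 slides. Slide 1 held replicate 1 of wild type at 30 °C, replicates 1 and 2 of wild type at 20 °C and replicate 1 of crhRTR at 20 °C. Slide 2 held replicate 2 of wild type at 30 °C, replicate 3 of wild type at 20 °C, and replicates 2 and 3 of crhRTR at 20 °C. Slide 3 held replicate 3 of wild type at 30 °C and all 3 arrays of crhRTR at 30 °C, so the cold response of crhRTR had no comparison within a slide.

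The procedure was tested on simulated data with 5694 features, of which 200 were changed. For the cold response of wild type it recovered 93.9% of 4-fold, 68.7% of 2-fold and 23.9% of 1.5-fold changes, with 3.88% of the calls false. For that of crhRTR the values were 95.5%, 58.2% and 16.4%, with 3.42% false. At 30 °C between strains they were 92.4%, 56.7% and 19.4%, with 6.67% false, and at 20 °C 90.9%, 50.7% and 28.4%, with 4.24% false. For the difference of the cold responses they were 84.8%, 34.3% and 0%, with 10.2% false. In simulated data for wild type, camera called the 1 list that was shifted and 0 of the others. The simulated genes varied independently and the lists were drawn at random. This therefore does not test how camera behaves on lists whose members vary together. The simulated arrays also carried no slide effect and no variation shared between features. Outside the difference of the cold responses, fewer features were changed there than were called in the data. The shares recovered and false therefore hold for such simulated arrays and do not cover effects of slide.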

Results

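RNA of wild type and of the partial crhR knockout crhRTR of the cyanobacterium Synechocystis was measured at 30 °C and after 3 h at 20 °C, with 3 arrays in each of the 4 groups. CrhR is an RNA helicase of the DEAD-box family, and the title of the series asks about it as a regulatory factor. On the wild-type arrays 66.0% to 73.3% of the probes were well above background, and on the crhRTR arrays 75.3% to 84.6%. Arrays of the same group correlated with r from 0.957 to 0.990 across features, and arrays of different groups with r from 0.827 to 0.962. Replicate 3 of crhRTR at 20 °C had the brightest 75th percentile (9153.14, against 2738.6 for the dimmest array) and the lowest mean of the 3 ribosomal RNA features (6.08, against 6.61 to 7.80 on the other arrays, log2).

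The targeted gene was read by 5 probes. On probe CUST_8630 of crhR (slr0083) the log2 signal, relative to the array's 75th percentile, was 0.71, 0.90 and 0.85 on the wild-type arrays at 30 °C and 3.10, 2.41 and 2.85 on those at 20 °C. On the crhRTR arrays this probe was above background on 0 of 3 arrays at either temperature, with −3.78, −3.83 and −3.36 at 30 °C and −5.22, −5.36 and −5.47 at 20 °C. Wild type was therefore at least 22.26-fold higher at 30 °C and at least 163.4-fold higher at 20 °C. The other 4 probes were above background in both strains. They rose in the cold by 1.67 to 2.00 (log2, limma adjusted p 0.00036 to 0.00124) in wild type and by 2.55 to 3.21 (adjusted p 5.7e-05 to 0.000111) in crhRTR. At 20 °C these 4 probes were 2.83-fold to 4.72-fold higher in crhRTR (adjusted p 0.0011 to 0.00452), and in log2 at 30 °C by 0.80 to 0.95, where adjusted p ran from 0.0417 to 0.0968. The mean over the 5 probes mixes the probe that was lost with those that were kept, and its strain differences were −0.20 ± 0.245 at 30 °C and −0.18 ± 0.245 at 20 °C (adjusted p 0.588 and 0.635).

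rimO (slr0082), which shares the locus with crhR and encodes a methylthiotransferase of a ribosomal protein, changed in the same directions as the 4 kept probes. Its rise in wild type was smaller than theirs, and its strain difference at 20 °C was larger. It rose by 1.05 ± 0.209 in wild type (adjusted p 0.00239) and by 3.20 ± 0.209 in crhRTR (adjusted p 4.82e-06) in the cold, and was higher in crhRTR by 2.98 ± 0.209 at 20 °C (adjusted p 2.76e-05). At 30 °C it was higher by 0.83 ± 0.209 (adjusted p 0.0199) and the call was lost without crhRTR at 30 °C replicate 1 (log2 0.75) or replicate 2 and with median scaling. Of the neighbours, sphR (slr0081) fell in wild type in the cold (−0.83 ± 0.149) and gave −0.10 ± 0.149 in crhRTR, where it was not called.

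**Figure D1:**
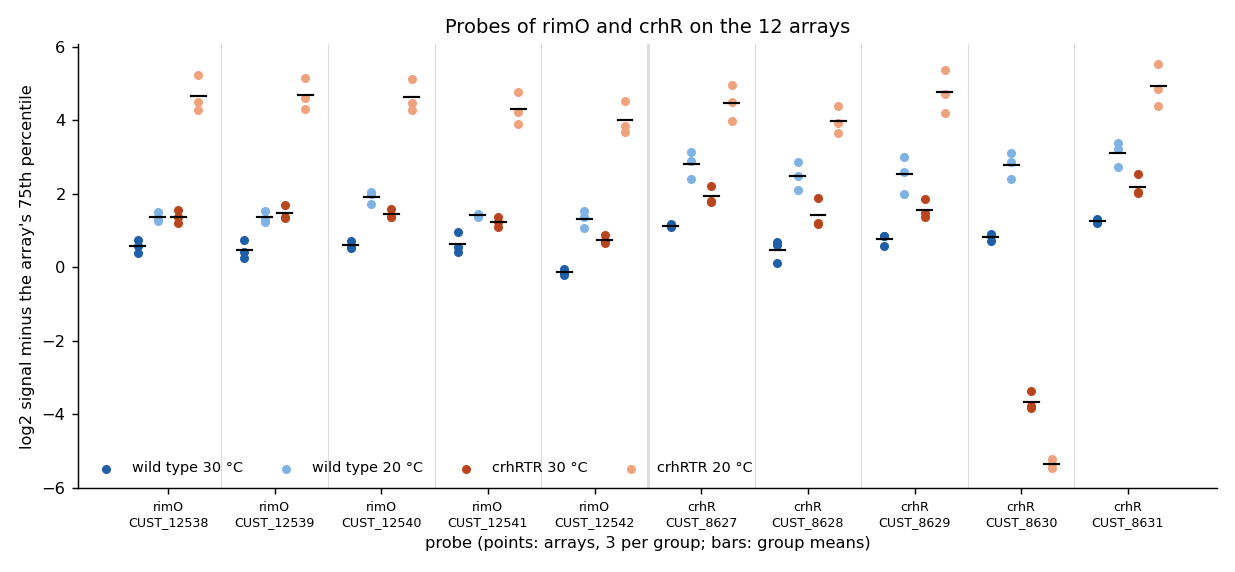
Log2 signal minus the array's 75th percentile for 5 probes each of rimO and crhR, with 1 point per array and a bar at the mean of the 3 arrays of a group. Probe CUST_8630 of crhR lay at −3.36 or lower on the 6 crhRTR arrays, while the other crhR probes and rimO were highest on the crhRTR arrays at 20 °C.

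The first comparison asked which transcripts responded to 3 h at 20 °C in wild type. All 52 ribosomal protein genes rose, with rplE (sll1808, 3.98 ± 0.539) and rpmC (ssl3436, 3.93 ± 0.568) among the largest rises, and so did genes for small light-protective proteins, with hliA (ssl2542, 4.71 ± 0.567) and hliB (ssr2595, 4.44 ± 0.695). The largest rise of an open reading frame was that of pgr5 (ssr2016), known for cyclic electron flow around photosystem I, by 5.05 ± 0.973 (adjusted p 0.00198). Of the photosystem I genes 11 of 12 fell, with psaK1 (ssr0390, −3.52 ± 0.373) (adjusted p 6.71e-05) and psaE (ssr2831, −3.38 ± 0.274). Of 5694 features, 2158 were called in limma, 878 higher and 1280 lower, and the median over all features was −0.15 (−0.154). With median scaling the split was 1022 and 1070 and the median −0.06.

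Genes reported earlier as cold-inducible behaved alike, since 19 of 21 rose and 0 fell (median log2 1.85, camera adjusted p 1.13e-10, adjusted p = 0.114 with an estimated correlation). Among them were the sigma factor gene sigD (sll2012, 1.83 ± 0.397) and slr1544 (3.90 ± 0.816). All 4 fatty acid desaturase genes rose (median 1.28, camera adjusted p 0.00284, adjusted p = 0.324 with an estimated correlation), with desB (sll1441, 2.06 ± 0.26) and desA (slr1350, 1.40 ± 0.254). The 4 high-light-inducible genes rose (median 3.31, adjusted p 0.00284, adjusted p = 0.34 with an estimated correlation). Of 15 heat shock and chaperone genes 7 rose and 2 fell (median 0.78, adjusted p 0.0235, adjusted p = 0.502 with an estimated correlation), with groES (slr2075, 2.30 ± 0.503), dnaK2 (sll0170, 2.28 ± 0.457) and htpG (sll0430, 2.23 ± 0.535). As measured by regrouping, other splits of the same 6 arrays gave up to 11 called lists in camera, beside the 15 called with the real one. The chaperone call was lost with quantile normalization, with normexp and quantile normalization and with slide as a block (adjusted p 0.0681, 0.0596 and 0.0717), without wild type at 30 °C replicate 3, and without wild type at 20 °C replicate 1, where the median was 0.49.

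Ribosomal protein genes rose in 52 of 52 cases (median 2.67, camera adjusted p 2.84e-29, adjusted p = 0.324 with an estimated correlation). Translation factor genes rose in 10 of 15 cases, 11 adjusted over the list alone (median 0.76, adjusted p 1.96e-05, adjusted p = 0.324 with an estimated correlation), with infA (ssl3441, 1.96 ± 0.204) and tsf (sll1261, 1.72 ± 0.282). Genes for ribonucleases and RNA processing rose in 5 of 8 cases (median 1.09, adjusted p 0.00748, adjusted p = 0.34 with an estimated correlation), including rnpA (slr1469, 1.83 ± 0.226), rnj (slr0551, 1.56 ± 0.287) and pnp (sll1043, 1.35 ± 0.239). Of the ATP synthase genes 9 of 10 rose, 10 adjusted over the list alone (median 1.27, adjusted p 0.000248, adjusted p = 0.502 with an estimated correlation), with atpG (sll1323, 1.42 ± 0.298) and atpF (sll1324, 1.38 ± 0.251). Here and below, counts adjusted over the list alone were the same as those over all features where only 1 count is given.

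Photosystem I genes fell in 11 of 12 cases, 12 adjusted over the list alone (median −2.32, camera adjusted p 2.19e-07, adjusted p = 0.34 with an estimated correlation), and psaD (slr0737, −3.01 ± 0.266) was another of them. Of 15 phycobilisome genes 12 fell and 1 rose (median −2.01, adjusted p 0.00211, adjusted p = 0.502 with an estimated correlation), with cpcB (sll1577, −2.41 ± 0.444) and cpcA (sll1578, −2.21 ± 0.393) for phycocyanin. Photosystem II genes fell in 12 of 26 cases (median −0.50, adjusted p 0.00242, adjusted p = 0.502 with an estimated correlation), with psbQ (sll1638, −1.60 ± 0.241) and psbB (slr0906, −1.32 ± 0.214). Genes of type IV pili and motility fell in 9 of 17 cases, 10 adjusted over the list alone (median −0.85, adjusted p 0.00284, adjusted p = 0.324 with an estimated correlation), with pilT1 (slr0161, −1.79 ± 0.222) and pilC (slr0162, −1.71 ± 0.178). For this list the median was −0.52 with normexp and quantile normalization. The NDH-1 list had 6 lower, 7 adjusted over the list alone, and 1 higher of 12 (median −0.90, adjusted p 0.0256, adjusted p = 0.629 with an estimated correlation), with ndhD1 (slr0331, −1.70 ± 0.163). That call was lost without wild type at 30 °C replicate 1 or 2 or wild type at 20 °C replicate 1. Cytochrome b6f and electron carrier genes fell in 4 of 11 cases (median −0.44, adjusted p 0.0278, adjusted p = 0.502 with an estimated correlation), with petD (slr0343, −1.14 ± 0.19). Its call was lost without wild type at 30 °C replicate 1 or wild type at 20 °C replicate 1.

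The lists below were not shifted in camera, but held members that changed. Chlorophyll and tetrapyrrole genes had 8 of 19 lower and 4 higher, with chlL (slr0749, −3.08 ± 0.308) and chlB (slr0772, −2.49 ± 0.292) of the light-independent protochlorophyllide reductase and chlP (sll1091, −2.15 ± 0.312). Nitrogen genes had 3 of 17 higher and 6 lower, with nblA1 (ssl0452, 2.38 ± 0.462), which acts in phycobilisome breakdown, and gifB (sll1515, 2.28 ± 0.333), an inhibitor of glutamine synthetase. Sugar catabolism had 2 of 12 higher and 6 lower, with glgX (slr0237, 1.99 ± 0.29) and glgP1 (sll1356, −2.40 ± 0.164), both for glycogen breakdown. Redox and photoprotection genes rose in 4 and fell in 4 of 16 cases, with ocp (slr1963, 2.00 ± 0.259) for the orange carotenoid protein and flv3 (sll0550, −1.74 ± 0.371) for a flavodiiron protein. Their median was −0.01 while their mean was 0.33. Sigma factor genes had 1 of 9 higher and 2 lower, among them sigF (slr1564, −1.57 ± 0.307). The phosphate regulon had 4 of 9 higher, with pstA (sll0682, 1.26 ± 0.267). The circadian clock had 3 of 9 higher, with rpaA (slr0115, 0.65 ± 0.146), and the iron list 2 of 11 lower, with bfrB (slr1890, −0.67 ± 0.178). The crhR locus had 2 of 4 higher and 2 lower. The carbon fixation list had 1 of 8 higher, 0 adjusted over the list alone. None of the 3 cytochrome oxidase, 12 inorganic carbon uptake or 16 CRISPR-associated genes was called.

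Among transcripts outside open reading frames, ncRNA_3330165:3330233 rose by at least 20.48-fold and ncRNA_700946:701128 by 3.56 ± 0.373. The antisense RNA asRNA_841933:842083, whose probe lies against rplC (sll1799), fell by at least 13.28-fold. By class, 36 antisense RNAs were higher and 161 lower.

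Every call in this comparison was tested with limma on 3 arrays against 3, and for 2606 of the 5694 features the groups did not overlap (45.8%, against 10% by chance). Within slides 1 and 2 the median of the ribosomal protein genes was 2.00 and 3.31, and that of the photosystem I genes −2.78 and −2.36. With fry, which tests a list without reference to other genes, all 15 lists called by camera here were called. It called 18 of the 28 lists, and 39.6% of the open reading frames were called, so fry does not show that these lists stand out.

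The second comparison asked the same of crhRTR. Of the ribosomal protein genes 44 of 52 rose, as did all 4 high-light-inducible genes, and all 12 photosystem I genes fell. Among the largest rises were those of hliA (5.09 ± 0.567) (adjusted p 9.64e-05), pgr5 (4.34 ± 0.973) and hliB (4.32 ± 0.695), and rimO was 1 of the 8 largest. cpcG2 (sll1471, −5.48 ± 1.12), a phycobilisome linker, and psaD (−4.04 ± 0.266) (adjusted p 4.82e-06) were among the largest falls, as was chlL (−3.70 ± 0.308). The call covered 2157 of 5694 features, 820 higher and 1337 lower, with a median over all features of −0.15 (−0.147). The split was 1124 higher and 1167 lower with quantile normalization, 1037 and 989 with median scaling, and 1044 and 1125 with normexp and quantile normalization. The median over all features was −0.03 (−0.0255) with quantile normalization and −0.01 (−0.0142) with median scaling.

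Of the 21 genes reported earlier as cold-inducible 19 rose (median 1.87, camera adjusted p 8.98e-13, adjusted p = 0.0672 with an estimated correlation), with slr1105 (1.70 ± 0.183). High-light-inducible genes rose in 4 of 4 cases (median 3.35, adjusted p 0.00106, adjusted p = 0.338 with an estimated correlation). Desaturase genes rose in 3 of 4 cases (median 0.63, adjusted p 0.0295, adjusted p = 0.338 with an estimated correlation), with desB (1.85 ± 0.26). That call was lost with quantile normalization, with normexp and quantile normalization and with slide as a block. Ribosomal protein genes rose in 44 of 52 cases (median 1.37, adjusted p 1.22e-15, adjusted p = 0.341 with an estimated correlation), with rplC (2.38 ± 0.611) and rplV (sll1803, 2.10 ± 0.521). Translation factor genes rose in 8 of 15 (median 0.64, adjusted p 0.000351, adjusted p = 0.338 with an estimated correlation), with prfB (sll1865, 1.32 ± 0.18) for a release factor. Genes for ribonucleases and RNA processing rose in 4 of 8 (median 0.75, adjusted p 0.0197, adjusted p = 0.338 with an estimated correlation), with rnj (1.99 ± 0.287). For them slide as a block gave a median of 0.48 and no call. Carbon fixation and carboxysome genes rose in 2 of 8 (median 0.60, adjusted p 0.0343, adjusted p = 0.521 with an estimated correlation). The carboxysome call was lost with quantile normalization, with normexp and quantile normalization, with median scaling, with slide as a block, without crhRTR at 30 °C replicate 3, where the median was 0.24, and without crhRTR at 20 °C replicate 2, where it was 0.39.

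All 12 photosystem I genes fell (median −2.62, camera adjusted p 5.37e-08, adjusted p = 0.338 with an estimated correlation), with psaK1 (−3.66 ± 0.373) and psaE (−3.32 ± 0.274). Phycobilisome genes fell in 12 of 15 cases, 13 adjusted over the list alone, and 1 rose (median −2.35, adjusted p 0.000351, adjusted p = 0.421 with an estimated correlation), with apcF (slr1459, −2.58 ± 0.303) and cpcG1 (slr2051, −2.48 ± 0.254). Photosystem II genes fell in 16 of 26 (median −0.79, adjusted p 0.000555, adjusted p = 0.434 with an estimated correlation), with psbB (−1.60 ± 0.214). Pili and motility genes fell in 11 of 17 and, adjusted over the list alone, 1 rose (median −0.88, adjusted p 0.0279, adjusted p = 0.338 with an estimated correlation), with pilC (−1.23 ± 0.178). The pili median was −0.57 with normexp and quantile normalization. Sugar catabolism genes fell in 7 of 12 and 1 rose (median −0.84, adjusted p 0.0169, adjusted p = 0.281 with an estimated correlation), with glgP1 (−2.84 ± 0.164) (adjusted p 2.53e-06). The sugar median was −0.54 with normexp and quantile normalization. Cytochrome b6f and electron carrier genes fell in 5 of 11 (median −0.58, adjusted p 0.0459, adjusted p = 0.499 with an estimated correlation). This call was lost with median scaling, with slide as a block, with a replicate block (adjusted p 0.0525) and without any of 5 arrays, among them crhRTR at 30 °C replicate 3, where the median was −0.38.

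CRISPR-associated genes fell in 11 of 16 cases in crhRTR, 12 adjusted over the list alone (median −1.37, camera adjusted p 9.92e-05, adjusted p = 0.338 with an estimated correlation), with sll7064 (−2.80 ± 0.231) and sll7067 (−2.47 ± 0.177). The median was −0.71 with slide as a block and −0.59 with normexp and quantile normalization. The ATP synthase list, called in wild type, had 1 of 10 higher, 0 adjusted over the list alone, and a median of 0.32 (adjusted p 0.0682). Without crhRTR at 30 °C replicate 3 or crhRTR at 20 °C replicate 1 the median was 0.56 and the list was called. Of the other lists, chlorophyll genes had 8 of 19 lower, 9 adjusted over the list alone, and 3 higher, with chlB (−3.29 ± 0.292). Heat shock genes had 3 of 15 higher, 2 adjusted over the list alone, and 1 lower. The heat shock list (median 0.39) was called with a replicate block and without any of 6 arrays, with medians of 0.60 without crhRTR at 30 °C replicate 1 and 0.68 without crhRTR at 20 °C replicate 1. Redox genes had 4 of 16 higher, 5 adjusted over the list alone, and 3 lower, with gpx2 (slr1992, 1.84 ± 0.324). Nitrogen genes had 3 of 17 higher and 2 lower, 1 adjusted over the list alone, with glnB (ssl0707, −1.66 ± 0.191), and a median of −0.03 beside a mean of 0.03. Iron genes had 5 of 11 lower, the phosphate regulon 1 of 9 lower, 0 adjusted over the list alone, and the NDH-1 complex 1 of 12 higher and 1 lower, with ndhD1 (−1.95 ± 0.163). Sigma factor genes had 1 of 9 higher and 3 lower, 4 adjusted over the list alone, with sigG (slr1545, −1.25 ± 0.221), and clock genes 2 of 9 higher and 1 lower, 2 adjusted over the list alone. The crhR locus had 2 of 4 higher and 1 lower, and none of the cytochrome oxidase or inorganic carbon uptake genes was called. The NDH-1 list (median −0.36) was called without crhRTR at 30 °C replicate 3, with −0.85. Inorganic carbon uptake (median 0.99) was called with a replicate block, without crhRTR at 30 °C replicate 1 or 2, with 1.79 for the latter, and without crhRTR at 20 °C replicate 3. Slide as a block called the tetrapyrrole list lower, with a median of −0.11 in place of −0.62.

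All 3 crhRTR arrays at 30 °C sat on slide 3, so no value of this comparison could be had within a slide, and with slide as a fixed block 356 features were called. In that fit hliA (5.48, adjusted p 0.0182), psaD (−4.11, adjusted p 0.00225), chlL, chlB, glgP1, rimO (3.05, adjusted p 0.00517), sll7064 and sll7067 were still called. By contrast, pgr5, hliB, cpcG2, rplC, rplV, rnj and psbB were not called (adjusted p 0.0529 to 0.319). By fry, without the block, 14 of the 15 lists called by camera were called, and the CO2 fixation and carboxysome list was not (adjusted p 0.148). Regrouping these 6 arrays gave up to 15 called lists in camera, as many as the real split.

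The overlap asked how much of the cold response the strains shared. There were 566 features higher in the cold in both strains, against 126.4 for independent calls, and 889 lower in both, against 300.6. A further 2 were called in opposite directions. Across features, which are not independent replicates, the log2 changes correlated with r = 0.826 and rho = 0.799. The shared calls with slide as a block numbered 316, and 1455 without it.

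**Figure D2:**
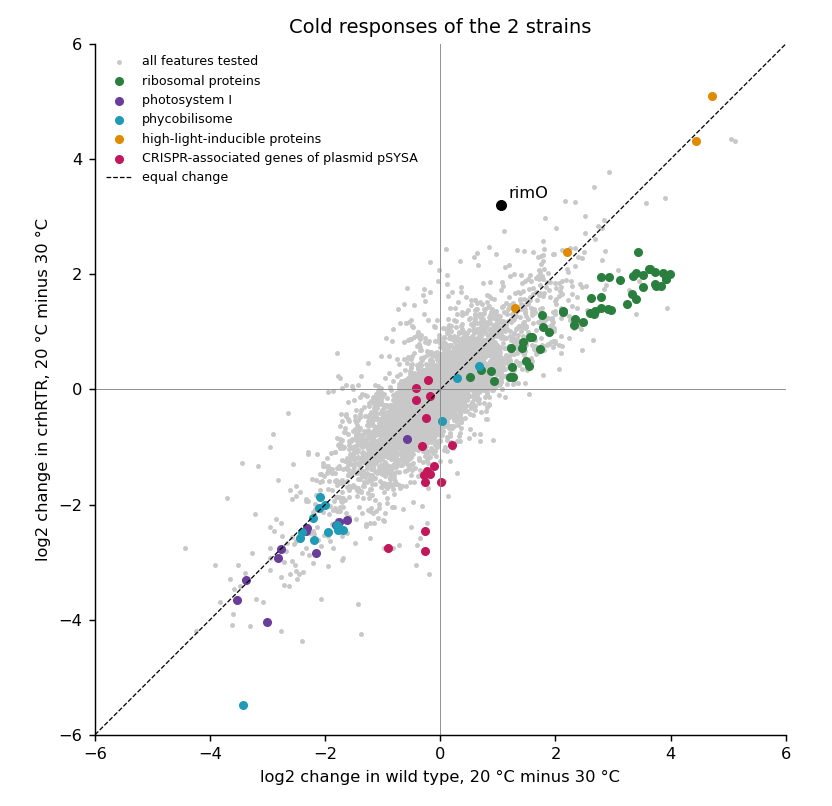
Log2 change in the cold in wild type (x axis) against that in crhRTR (y axis) for the 5694 features tested, with members of 5 gene lists in colour and a dashed line of equal change. Photosystem I and phycobilisome genes lie low in both strains, ribosomal protein genes lie below the line (medians 2.67 and 1.37), CRISPR-associated genes lie lower in crhRTR, and rimO lies above the line (1.05 and 3.20).

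The third comparison asked how the strains differed at 30 °C. Transcripts higher in crhRTR outnumbered those lower, and the largest rises among open reading frames included sll1863 (4.47 ± 0.307) (adjusted p 1.23e-05), ssr2062 (3.72 ± 0.332) and sigE (sll1689, 3.16 ± 0.267) (adjusted p 3.62e-05), which encodes a sigma factor of sugar catabolism. Of the CRISPR-associated genes 9 of 16 were higher and of the sugar catabolism genes 5 of 12, while 6 of 16 redox and photoprotection genes were lower. The largest value on the lower side was that of flv4 (sll0217, −4.07 ± 1.28), a flavodiiron protein of photosystem II protection (adjusted p 0.0448). The call of flv4 was lost with quantile normalization and without any of 9 arrays, and −1.98 without crhRTR at 30 °C replicate 3. Calls numbered 1099 of 5694, 825 higher and 274 lower (median over all features 0.18). Their number was 407 without wild type at 30 °C replicate 2, and 475, 654 and 696 without crhRTR at 30 °C replicates 2, 3 and 1. Higher and lower calls numbered 626 and 466 with quantile normalization, 535 and 437 with median scaling, 576 and 429 with normexp and quantile normalization, and 574 and 459 with the deposited values. They numbered 467 and 276 with normexp on the mean raw intensity where deposited, and 454 and 250 with normexp on the median raw intensity of all arrays. Over all features the median was 0.03 (0.0295 with quantile normalization and 0.031 with median scaling). With only the probes above background on all 12 arrays, which left 4768 features, the calls were 472 higher and 336 lower. The median was then 0.04 (0.0399).

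CRISPR-associated genes were higher in 9 of 16 cases, 10 adjusted over the list alone (median 1.17, camera adjusted p 0.000253, adjusted p = 0.684 with an estimated correlation), with sll7063 (2.43 ± 0.204) and with sll7064 at least 3.71-fold higher. The median was 0.70 with slide as a block and 0.37 with normexp and quantile normalization. Sugar catabolism genes were higher in 5 of 12 cases, 7 adjusted over the list alone (median 0.60, adjusted p 0.0218, adjusted p = 0.286 with an estimated correlation), with gnd (sll0329, 1.19 ± 0.204) and gap1 (slr0884, 1.61 ± 0.292). The value of gap1 was −0.10 with only the probes above background on all 12 arrays, the sugar list's median was 0.34 with normexp and quantile normalization, and its call was lost without wild type at 30 °C replicate 3. Redox and photoprotection genes were lower in 6 of 16 cases, 8 adjusted over the list alone, and 1 was higher (median −0.70, adjusted p 0.000321, adjusted p = 0.286 with an estimated correlation), with flv4 among the lower ones. Genes for inducible inorganic carbon uptake were lower in 2 of 12 cases, 1 adjusted over the list alone (median −2.13, adjusted p 0.000253, adjusted p = 0.684 with an estimated correlation). The carbon uptake median was −0.77 without crhRTR at 30 °C replicate 3. One of its members was ndhD3 (sll1733, −2.19 ± 0.697), a call lost without any of 9 arrays and −1.11 without crhRTR at 30 °C replicate 3.

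The NDH-1 complex had 5 of 12 lower, 8 adjusted over the list alone, and 1 higher (median −0.89, camera adjusted p 0.00357, adjusted p = 0.684 with an estimated correlation), with ndhD1 (1.38 ± 0.163) as the higher one. The median was −0.46 without crhRTR at 30 °C replicate 3. Its call was lost with quantile normalization, with normexp and quantile normalization and with slide as a block. Cytochrome b6f and electron carrier genes were lower in 5 of 11 cases and 1 was higher (median −0.44, adjusted p 0.00313, adjusted p = 0.684 with an estimated correlation), with petD (−0.88 ± 0.19) and petB (slr0342, −0.85 ± 0.191). The calls of both were lost without wild type at 30 °C replicate 2. The list's call was lost with quantile normalization, and its median was −0.73 without crhRTR at 30 °C replicate 3. ATP synthase genes were lower in 1 of 10 cases (median −0.51, adjusted p 0.00349, adjusted p = 0.684 with an estimated correlation). The ATP synthase call was lost with quantile normalization, with normexp and quantile normalization and without wild type at 30 °C replicate 1, where the median was −0.29. The cold-inducible list was lower (median −0.29, adjusted p 0.0345, adjusted p = 0.684 with an estimated correlation), with 2 of 21 higher and 2 lower, 3 adjusted over the list alone. Its median was −0.46 without wild type at 30 °C replicate 1, and −0.55 without wild type at 30 °C replicate 3 or crhRTR at 30 °C replicate 1. Translation factors were lower as a list (median −0.22, adjusted p 0.0296, adjusted p = 0.684 with an estimated correlation), with 0 of 15 called. Photosystem II was lower too (median −0.14, adjusted p 0.0162, adjusted p = 0.684 with an estimated correlation), with 2 of 26 lower, 1 adjusted over the list alone. Each of these 3 calls was lost with quantile normalization, with normexp and quantile normalization and with slide as a block. Of the left-out arrays, wild type replicate 2 or crhRTR replicate 3 ended the first, wild type replicate 1 or crhRTR replicate 2 the second, and crhRTR replicate 1 or 2 the third, all at 30 °C. Median scaling also ended the first call and gave medians of −0.37 for translation factors and −0.29 for photosystem II. The photosystem II median was 0.01, −0.06 and −0.38 without crhRTR at 30 °C replicate 1, 2 and 3.

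Of the lists not shifted, ribosomal proteins had 3 of 52 higher, 0 adjusted over the list alone, with a median of 0.40 (adjusted p 0.244). This list was called higher with quantile normalization, with normexp and quantile normalization and with slide as a block (adjusted p 0.00193, 0.000603 and 0.0376). It was also called higher without wild type at 30 °C replicate 1 (median 0.83) and without crhRTR at 30 °C replicate 2 (median 0.68). Photosystem I genes, with a median of 0.58, were called higher as a list with the same 3 settings (adjusted p 0.0426, 0.0252 and 0.00384) and without wild type at 30 °C replicate 1 (median 0.89) or crhRTR at 30 °C replicate 1 or 2. Cytochrome oxidase had 2 of 3 higher, 3 adjusted over the list alone, the pili list 3 of 17 higher, 4 adjusted over the list alone, and the phycobilisome 2 of 15 higher. The sigma factor list held 1 called gene of 9, sigE, with a median of −0.01 beside a mean of 0.33. Heat shock genes had 1 of 15 lower, clpC (sll0020, −1.16 ± 0.213), with a median of 0.18 against a lower direction in camera. The phosphate regulon and the circadian clock had 1 of 9 higher each. Iron genes had 2 of 11 lower, with a median of 0.04 beside a mean of −0.05, and the tetrapyrrole list 2 of 19 lower, 0 adjusted over the list alone, with a median of 0.09 against a lower direction in camera. The crhR locus had 1 of 4 higher, 2 adjusted over the list alone. No desaturase, high-light-inducible, photosystem I, carbon fixation, nitrogen or ribonuclease gene was called. Left-out arrays gave further list calls, which were the high-light-inducible genes (−1.33) and the phycobilisome (0.62) without wild type at 30 °C replicate 1, and cytochrome oxidase (0.89) without wild type at 30 °C replicate 2. Carbon fixation was called lower without wild type at 30 °C replicate 2 (−0.35) or crhRTR at 30 °C replicate 1 (−0.42) or 2 (−0.49) and with a replicate block. Slide as a block called the phycobilisome (0.45) and the pili list (0.34), and quantile normalization, alone or with normexp, called cytochrome oxidase.

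Outside open reading frames, ncRNA_2676454:2676709 was higher by 5.49 ± 0.527 and 5'UTR_1052431:1052517 by at least 20.88-fold. The internal transcript intern_2225554:2225701, whose probe lies within sll1862, was higher by 3.73 ± 0.294. Of the antisense RNAs 123 were higher and 15 lower.

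The 3 crhRTR arrays at 30 °C shared slide 3 with 1 wild-type array. In a fit with slide as a block 107 features were called, among them sll1863 (4.54), sigE (3.36, adjusted p 0.0055), ssr2062, ndhD1, sll7063 and sll7064, while clpC, gnd, gap1, flv4, ndhD3, petB and petD were not. By fry, without the block, only the redox, sugar catabolism and CRISPR-associated lists of the 10 were called, and the other 7 were not (adjusted p 0.107 to 0.486). In camera, other splits of these 6 arrays gave up to 18 called lists, more than the 10 of the real one. Within slide 3 the CRISPR-associated median was 0.70 and that of ATP synthase −0.53.

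**Figure D3:**
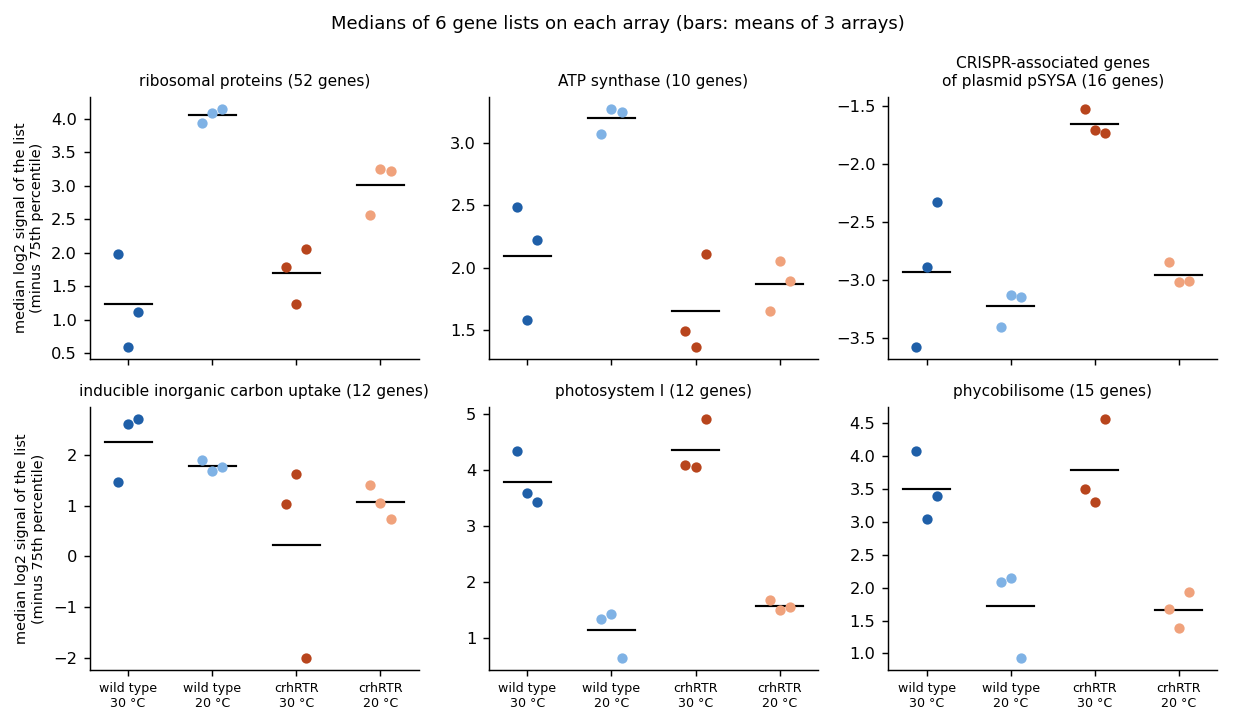
Median log2 signal, relative to the array's 75th percentile, of 6 gene lists on each of the 12 arrays, with bars at the means of the 3 arrays of a group; each panel has its own y axis. Ribosomal protein and ATP synthase genes were lower in crhRTR than in wild type at 20 °C, CRISPR-associated genes were highest in crhRTR at 30 °C, and replicate 3 of crhRTR at 30 °C lay apart for inorganic carbon uptake.

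The fourth comparison asked how the strains differed after 3 h at 20 °C. Of the ATP synthase genes 9 of 10 were lower in crhRTR and of the ribosomal protein genes 14 of 52. The largest rise of an open reading frame was that of rimO (2.98 ± 0.209). sigE (1.93 ± 0.267) was higher as at 30 °C, and pilN (slr1275, 1.39 ± 0.247), a pilus assembly gene, was higher too. Among the largest falls were slr1622 (−1.92 ± 0.176) and slr0452 (−1.88 ± 0.159). Calls numbered 1417 of 5694, 1003 higher and 414 lower (median over all features 0.11). That split was 785 and 575 with median scaling, 695 and 463 with the deposited values, 570 and 495 with normexp on the mean raw intensity where deposited, and 562 and 488 with normexp on the median raw intensity of all arrays. The median over all features was 0.03 with quantile normalization, 0.00 (0.00149) with median scaling and −0.04 (−0.0351) with either form of normexp. With only the probes above background on all 12 arrays, the split was 564 and 446 and the median −0.03 (−0.0253).

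ATP synthase genes were lower in 9 of 10 cases (median −1.44, camera adjusted p 3.11e-06, adjusted p = 0.593 with an estimated correlation), with atpC (sll1327, −1.56 ± 0.307), atpG (−1.48 ± 0.298) and atpA (sll1326, −1.46 ± 0.307). Ribosomal protein genes were lower in 14 of 52 cases, 30 adjusted over the list alone (median −0.84, adjusted p 6.51e-12, adjusted p = 0.617 with an estimated correlation). Translation factor genes were lower in 5 of 15, 6 adjusted over the list alone (median −0.26, adjusted p 0.00361, adjusted p = 0.593 with an estimated correlation), with tsf (−1.42 ± 0.282) and infA (−1.10 ± 0.204). The list's call was lost with quantile normalization and with normexp and quantile normalization. Without wild type at 20 °C replicate 1 the translation median was −0.40. Photosystem II genes were lower in 6 of 26 cases (median −0.43, adjusted p 0.0111, adjusted p = 0.838 with an estimated correlation), with psbF (smr0006, −0.80 ± 0.165). Redox genes were lower in 4 of 16 cases, 5 adjusted over the list alone, and 1 was higher (median −0.66, adjusted p 0.0252, adjusted p = 0.593 with an estimated correlation), with slr1198 (−1.42 ± 0.172). Cytochrome b6f and electron carrier genes were lower in 3 of 11 (median −0.23, adjusted p 0.02, adjusted p = 0.617 with an estimated correlation), with petA (sll1317, −0.87 ± 0.203). Tetrapyrrole genes were lower in 2 of 19 (median −0.30, adjusted p 0.0252, adjusted p = 0.593 with an estimated correlation).

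Calls of photosystem II, redox, cytochrome and tetrapyrrole genes were each lost with quantile normalization, with normexp and quantile normalization and without wild type at 20 °C replicate 2. Slide as a block also ended the tetrapyrrole call (adjusted p 0.0591). The photosystem II, redox and cytochrome calls were also lost without crhRTR at 20 °C replicate 3, and the redox call without crhRTR at 20 °C replicate 1 (median −0.45) and with median scaling. The photosystem II median was −0.21 with quantile normalization, and the cytochrome median −0.46 without wild type at 20 °C replicate 3, −0.35 without crhRTR at 20 °C replicate 2 and −0.11 with normexp and quantile normalization.

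Of the lists not shifted, the pili list had 4 of 17 higher and 1 lower, with pilO (slr1276, 0.95 ± 0.194), and sugar catabolism 3 of 12 higher and 1 lower, with gnd (0.87 ± 0.204). The crhR locus had 2 of 4 higher, the cold-inducible list 2 of 21 higher and 1 lower, with sll1911 (−1.44 ± 0.328), and the desaturases 1 of 4 lower, 2 adjusted over the list alone, with desC (sll0541, −0.79 ± 0.17). Heat shock genes had 1 of 15 higher and 2 lower, with clpC (−0.96 ± 0.213). Iron genes had 2 of 11 lower, with bfrA (sll1341, −0.98 ± 0.158) for a bacterioferritin and a list median of 0.23 against a lower direction in camera. The NDH-1 complex had 1 of 12 higher, ndhD1 (1.14 ± 0.163), and nitrogen 1 of 17 higher and 1 lower, 0 adjusted over the list alone. Phycobilisome genes had 2 of 15 higher and CRISPR-associated genes 2 of 16, which were 0 and 1 adjusted over the list alone. Cytochrome oxidase, ribonucleases, sigma factors, the clock and the phosphate regulon had 1 member higher each, 0 adjusted over the list alone for the phosphate regulon. The ribonuclease median was −0.13 beside a mean of 0.02, and the clock median of 0.06 stood against a lower direction in camera. No high-light-inducible, photosystem I, carbon fixation or inorganic carbon gene was called. Single left-out arrays, at either temperature, gave list calls for the cold-inducible (−0.39), desaturase, NDH-1, inorganic carbon and pili lists, with medians moved by less than a factor of 1.5. Normexp with quantile normalization called the crhR locus (0.54).

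Antisense RNAs were higher in crhRTR in 212 of 703 cases and lower in 11 (median 0.39), against 513 and 329 of 3521 open reading frames (median 0.06). Non-coding RNAs (69 higher and 7 lower of 298) and internal transcripts (141 and 26 of 654) leaned the same way, and 5' UTRs less so (68 and 41 of 474). asRNA_487226:487313 was higher by at least 7.558-fold, and ncRNA_2676454:2676709 was higher by 3.90 ± 0.527, as at 30 °C. The share of probes above background was also higher on each crhRTR array than on any wild-type array.

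The difference at 20 °C could be read within slides. On slides 1 and 2 the median of the ATP synthase genes was −1.73 and −1.27, and that of the ribosomal protein genes −1.10 and −0.75. By fry the ribosomal protein and cytochrome lists were not called (adjusted p 0.0924 for both), nor were photosystem II (0.211) and the tetrapyrrole genes (0.0791), while the other 3 were. Up to 13 lists were called in camera with other splits of these 6 arrays, more than the 7 of the real one. The count of features was 759 without wild type at 20 °C replicate 3 and 922 without crhRTR at 20 °C replicate 1.

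**Figure D4:**
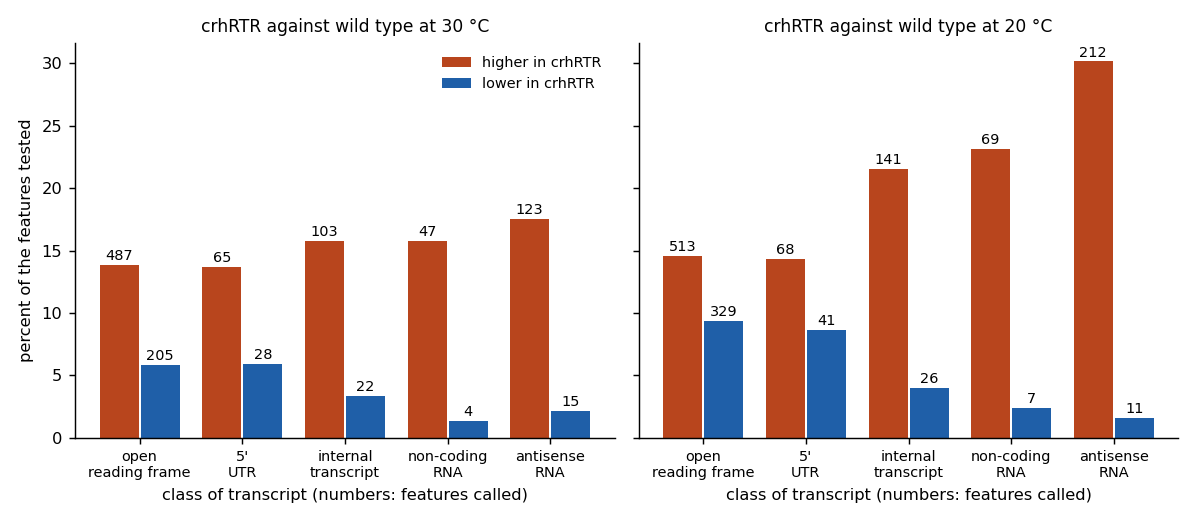
Percent of the tested features of 5 transcript classes that were called higher or lower in crhRTR than in wild type, at 30 °C (left) and 20 °C (right), with the numbers of features above the bars. At 20 °C 212 antisense RNAs were higher and 11 lower, against 513 and 329 open reading frames. Non-coding RNAs (69 and 7) and internal transcripts (141 and 26) leaned the same way.

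Between the temperatures, 502 features were higher in crhRTR at both, against 145.3 for independent calls, 125 were lower at both, against 19.92, and 0 were called in opposite directions in limma. The strain differences at the 2 temperatures correlated across features with r = 0.657 and rho = 0.642.

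The last comparison asked which cold responses differed between the strains. In crhRTR the rise of rimO was larger, by 2.15 ± 0.296 (adjusted p 0.0122). CRISPR-associated genes fell in crhRTR, with a difference of −2.20 ± 0.25 for sll7067. Between the strains sll7067 was higher in crhRTR by 2.09 at 30 °C and was not called at 20 °C (−0.12). The fall of sll7064 in crhRTR had no measured counterpart, since its probes were dim on the wild-type arrays at both temperatures. Ribosomal protein genes rose less in crhRTR as a list, with a median difference of −1.20 (camera adjusted p 1.79e-20, adjusted p = 0.713 with an estimated correlation), where 0 of 52 were called singly and 34 adjusted over the list alone. Calls numbered 24 of 5694, 9 higher and 15 lower, of which 13 were open reading frames, and 689 features had an unadjusted p under 0.05. The number was 5 without crhRTR at 30 °C replicate 2 and 48 without wild type at 20 °C replicate 1. It was 3 with either form of normexp alone, 7 with only the probes above background on all 12 arrays, and 10 with the median of the probes. The split was 18 and 14 with quantile normalization, 16 and 12 with median scaling, 8 and 8 with normexp and quantile normalization, and 25 and 23 with the deposited values.

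The CRISPR-associated list differed by a median of −1.20, with 4 of 16 called, 9 adjusted over the list alone (adjusted p 6.08e-08, adjusted p = 0.385 with an estimated correlation), and −0.47 with normexp and quantile normalization. In wild type, where 0 of 16 were called, the array medians of this list were −3.58 to −2.33 at 30 °C and −3.40 to −3.13 at 20 °C. At 20 °C, and for the lower values at 30 °C, they lay near the detection floors of those arrays (−3.85 to −3.43). The room for a fall in wild type was therefore limited. The highest value, −2.33 at 30 °C, lay above the floors, so the floors may not account for the whole difference. ATP synthase genes differed by −0.83 (adjusted p 0.00408, adjusted p = 0.747 with an estimated correlation, 0 of 10 called), a call lost without crhRTR at 30 °C replicate 3. Genes for inorganic carbon uptake differed by 1.44 (adjusted p 0.0136, adjusted p = 0.747 with an estimated correlation, 0 of 12 called). This was 0.13 and lost without crhRTR at 30 °C replicate 3, 2.28 without crhRTR at 30 °C replicate 2, and lost without wild type at 20 °C replicate 1. Sugar catabolism differed by −0.45 (adjusted p 0.0157, adjusted p = 0.229 with an estimated correlation, 0 of 12 called, 1 adjusted over the list alone), lost without wild type at 30 °C replicate 1 or 3. The crhR locus differed by 0.38 (adjusted p 0.0157, adjusted p = 0.229 with an estimated correlation), through rimO and, adjusted over the list alone, 1 more gene of the 4, and 0.60 with quantile normalization. Its call was lost with slide as a block. The other 22 lists were not shifted, and among their members rimO, in the cold-inducible list, was the only one called. The NDH-1 list (median 0.43) was called with a replicate block and without any of 5 arrays, with 0.74 without crhRTR at 30 °C replicate 1. Photosystem I was called without wild type at 30 °C replicate 1 (−0.48) or wild type at 20 °C replicate 3 (−0.44), and the phycobilisome without the latter (−0.55). Nitrogen was called without crhRTR at 30 °C replicate 3 (0.49), pili without wild type at 30 °C replicate 3 (0.32), the cold-inducible list without crhRTR at 20 °C replicate 3 (0.24), and translation factors with slide as a block (−0.23). For the cold-inducible, cytochrome b6f and iron lists the medians of −0.00434, −0.08 and −0.07 stood against a higher direction in camera.

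The probe of crhR that was lost in the mutant was not above background in crhRTR at either temperature, so its cold response there was not measured. The other 4 probes gave differences of 0.55 to 1.44 (adjusted p 0.226 to 0.626). By fry the ribosomal protein, ATP synthase and inorganic carbon lists were not called (adjusted p 0.184, 0.488 and 0.651), and the other 3 lists were. Of 100 splits of the arrays within strains, 84 gave at least the 6 lists called in camera. With slide as a fixed block 0 of 5694 features were called in limma, with standard errors that rest on 1 wild-type array for slide 3. The call of rimO was lost without crhRTR at 30 °C replicate 2 (adjusted p 0.0517), while those of sll7064 and sll7067 held without any single array and were lost with normexp on the mean or the median raw intensity. That of sll7067 was also lost with the deposited values, with only the probes above background on all 12 arrays and with the median of the probes.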

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

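The tests of array scaling and of slides for the antisense RNAs, and the test for a smaller response in crhRTR, were chosen only after the result was seen. The inorganic carbon uptake genes were also first weighed as a pattern and then replaced by the antisense RNAs after its results and the counts of antisense RNAs had been seen, so their values are given here: the median strain difference at 30 °C was −2.13, −2.16 with quantile normalization, −2.28 with median scaling, −2.73 with slide as a block, and −0.77 without crhRTR at 30 °C replicate 3.

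A difference of the cold responses, tested as an interaction in limma, singled out 24 features. Of the open reading frames, rimO responded more strongly in crhRTR (2.15). The responses of slr0675 (−2.63), sll7064 (−2.54), sll1863 (−2.53), sll7070 (−2.24), sll7067 (−2.20), slr0334 (−1.89) and sll7063 (−1.62) lay lower in crhRTR. At 30 °C slr0675, sll7064, sll7070 and sll7067 were higher in crhRTR (2.57, 2.50, 2.11 and 2.09). At 20 °C they were not called (−0.06, −0.04, −0.13 and −0.12). sll1863, slr0334 and sll7063 were higher at both, by 4.47, 3.44 and 2.43 at 30 °C against 1.94, 1.55 and 0.81. The lower responses of the open reading frames named here thus go with a higher level at 30 °C in crhRTR, whose arrays there all sat on slide 3. Some other open reading frames with lower responses, not named here, were not called between strains at 30 °C (0.12, 0.21 and 0.25). They lay lower in crhRTR at 20 °C (−0.855, −0.94 and −0.93), a comparison without slide 3. Of the other features, ncRNA_2655184:2655237 (2.35), ncRNA_1413998:1414089 (2.34) and intern_914936:915052 (1.87) lay higher, and 5'UTR_2325819:2325863 (−3.00), 5'UTR_1072919:1072972 (−2.87) and 5'UTR_2389901:2390038 (−1.94) lower. Those 5' UTRs too were higher in crhRTR at 30 °C (2.63, 2.24 and 1.81) and not called at 20 °C. Probe CUST_8630 of crhR gave −3.66, which is not a measured difference, since its crhRTR signals were background at both temperatures. Likewise slr0675, sll7064, sll7070, ncRNA_2655184:2655237 and 5'UTR_1072919:1072972 were dim on the wild-type arrays at both temperatures, and 5'UTR_2325819:2325863 and 5'UTR_2389901:2390038 in at least 1 group, so the sizes of their differences depend on the background. Without crhRTR at 30 °C replicate 2 the count was 5, and without wild type at 20 °C replicate 1 it was 48. The calls of sll7064, sll7067, sll7070 and 5'UTR_1072919:1072972 held without any single array, that of rimO was lost without crhRTR at 30 °C replicate 2, and each other feature named here, apart from the crhR probe, lost its call without at least 4 of the arrays. In a fit with slide as a block 0 features were called in limma.

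The same interaction, tested in camera, singled out the ribosomal proteins (−1.20), CRISPR-associated genes (−1.20), ATP synthase (−0.83), sugar catabolism (−0.45), the crhR locus (0.38) and inorganic carbon uptake (1.44). None of the 6 calls held with an estimated correlation, and those of ribosomal proteins, ATP synthase and inorganic carbon did not hold with fry (adjusted p 0.184, 0.488 and 0.651). The CRISPR-associated genes had limited room to fall in wild type. The lower of their array medians there (−3.58 to −2.33) lay near the detection floors (−3.85 to −3.43), while the highest lay above them. The inorganic carbon value was 0.13 without crhRTR at 30 °C replicate 3. On crhRTR at 30 °C replicate 3 the median signal of that list was −1.999 (log2), against 0.73 to 2.71 on the other arrays. No outlier test of single arrays was run in groups of 3.

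Of the 24 features, 4 had the smaller absolute response in crhRTR (16.7%), so by this count a smaller response does not describe most of them. The count includes the features named above as dim on the wild-type arrays at both temperatures. Their wild-type response was not measured, so their place in the count decides nothing. The count also says nothing of other genes: across all features the slope of the crhRTR on the wild-type response was 0.808, and the ribosomal protein median was 1.37 in crhRTR and 2.67 in wild type. Among 100 of the 200 possible splits of the arrays within strains, 7 gave as many features as the real 24. The highest other value was 3052, from a split that kept the wild-type groups and exchanged the crhRTR temperatures. Each of the other 6 splits kept the wild-type groups or exchanged the crhRTR temperatures, so it carried a cold effect, which is a structure of the samples. The share is not under 0.05, so chance in the grouping is not excluded by this count, and such splits do not show chance either.

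Antisense RNAs were higher in crhRTR at 20 °C, with a median of 0.39 (212 higher, 11 lower of 703). Open reading frames matched to them in signal level gave a median of 0.0503 (bootstrap standard error 0.0237, 84 higher, 60 lower). This argues against the mean level of a feature as the whole cause. Dimness of single probes was not matched. Open reading frames held more probes each (17206 for 3623 frames, against 1216 for 837 antisense RNAs). The antisense median was not tested with normexp alone or with only the probes above background on every array. Those settings moved the median over all features from 0.109 to −0.0351 and −0.0253. A lift of dim spots therefore remains open. The antisense median was 0.275 with quantile normalization and 0.279 with median scaling. In the fit with slide as a block it was 0.416, and within slides 1 and 2 it was 0.507 and 0.387, so neither scaling nor slide accounts for all of it. The lean was not particular to antisense RNAs. At 20 °C non-coding RNAs had 69 higher and 7 lower, internal transcripts 141 and 26, and 5' UTRs 68 and 41. An effect of the strain on several classes of transcript may underlie it, but the mutant's medium differed too and was not separated from strain.

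In camera, the ribosomal protein list rose less in the cold in crhRTR (median difference −1.20), but 0 of 52 members were called singly and the list call did not hold with an estimated correlation (adjusted p 0.713) or with fry (0.184). The strain difference at 20 °C, −1.10 on slide 1 and −0.75 on slide 2, did not involve slide 3, so that slide cannot account for that part. No single array carried this, since the value nearest to 0 was −0.9593, without wild type at 30 °C replicate 2, and no scaling did, since the median was −0.9837 with quantile normalization and −1.156 with median scaling. Slide as a block gave −1.203, with a standard error of the list mean of 0.707 and a camera adjusted p of 3.87e-21. That value met the bound set beforehand against slide 3, but for the part at 30 °C the bound was insufficient and slide, strain and medium cannot be told apart, since all 3 crhRTR arrays at 30 °C are on slide 3, whose effect rests on 1 wild-type array.

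The CRISPR-associated list was higher in crhRTR at 30 °C in camera (median 1.17, 9 of 16 called), but the list call did not hold with an estimated correlation (adjusted p 0.684) and the median was 0.3733 with normexp and quantile normalization. The 83 other open reading frames with tags of the same number series had a median of 0.437 (bootstrap standard error 0.0903). This met the bound set beforehand against a higher plasmid copy number as the whole cause. The frames were not matched to the list in signal level, so the value does not decide this, and copy number could account for part. Frames of number series 5, 6 and 8 had medians of 0.386, 0.398 and 0.528 at 30 °C. No single array carried the list's difference, with 0.9312 without wild type at 30 °C replicate 1 as the value nearest to 0. Slide as a block gave a median of 0.7002 (standard error of the list mean 0.157, camera adjusted p 0.00545), which met the bound set beforehand, but for the reason given for the ribosomal genes that bound was insufficient. Slide 3, strain and medium cannot be told apart here. Dim signal was not tested as a cause of this pattern, though the lower of the wild-type array medians of the list lay near the detection floors, as given above.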

How the results depend on the processing

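The alternatives with normexp on the median raw intensity and with values floored at the detection limit were chosen after seeing the data. Of the values of single genes and features under all alternatives, 15837 kept direction and side of the threshold, 228 passed it anew, 865 no longer passed and 7 reversed. For the gene lists 2447 kept both, 67 passed anew, 146 no longer passed and 0 reversed. The cause was not tested for any change below, except where fewer arrays or a stricter criterion make it.

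With each probe on its own, which raises the number tested, the calls were 6247 for the cold in wild type, 6258 for the cold in crhRTR, 2757 between strains at 30 °C, 3583 at 20 °C and 50 for the difference of the cold responses. With an absolute log2 change of at least 1 the first 4 were 1025, 1000, 405 and 521. With slide as a fixed block they were 1748, 356, 107 and 1422, with 0 for the difference and 316 shared between the cold responses; the 356, 107 and 0 rest on the comparisons in which slide 3 holds a group entirely. At 30 °C, a fit of 2 groups only gave 591, and normexp on the median raw intensity 704.

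The difference of the cold responses was the least stable count. It was 3 with normexp on the mean or, where absent, the median raw intensity, 3 with normexp on the median raw intensity of all arrays, 48 with the deposited values and 43 with floored values. Only probes above background on all 12 arrays gave 7, the median of the probes 10, a replicate block 13 and an intensity trend 14. With an estimated correlation 0 of the 53 list calls held in camera.

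Leaving out 1 array gave 1526 to 2171 calls for the cold in wild type and 1455 to 2288 for the cold in crhRTR. At 30 °C the range was 407, without wild type at 30 °C replicate 2, to 1256, with 475 and 654 without crhRTR at 30 °C replicates 2 and 3 and 696 without replicate 1. At 20 °C it was 759, without wild type at 20 °C replicate 3, to 1525, with 922 without crhRTR at 20 °C replicate 1. For the difference it was 5, without crhRTR at 30 °C replicate 2, to 48, without wild type at 20 °C replicate 1. Where 2 arrays were left in a group, the fit pooled the spread of all groups. Residual correlations of arrays with the same replicate number ran from −0.413 to 0.461 over 18 pairs, with 6 over 0.1. Between the strains at 30 °C all 3 were (0.252, 0.454 and 0.219), and the count there was 1012 with a replicate block.

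Reversed values were these. slr7014 gave 0.42 in the cold in crhRTR with slide as a block, and gap1 gave −0.10 (−0.0995) at 30 °C with only the probes above background on all 12 arrays. The mean over the probes of crhR gave 0.87 at 30 °C with that filter, which removes its lost probe. At 20 °C it gave 1.81 with that filter, 1.70 with the median of the probes, 0.65 with normexp and quantile normalization and 0.93 with the deposited values. Signal over background limits the reading of dim features, since at most 84.6% of the probes of an array were well above background.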

Other observations

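The counts by tag series and of structural RNAs were made only after the data were seen, while the tests of strand pairs and of splits were planned. Open reading frames whose tags belong to number series 5 to 8, which general knowledge places on plasmids, rarely rose in the cold in wild type, with 2.56%, 1.35%, 2% and 0% higher, against 19.9% of the 3184 with tags of series 0 to 3. Lower calls there were 22 of 117, 13 of 74, 12 of 100 and 8 of 46, against 700 of the 3184. Between strains at 30 °C, 25.6%, 31.1%, 32% and 34.8% of the 4 series were higher in crhRTR, against 12.1%, and at 20 °C 28.2%, 23%, 27% and 45.7%, against 13%. Signal level was not matched between the series for any of these shares. Of the 44 structural RNAs, 1 fell in the cold in wild type and 3 in crhRTR; 6803s01 fell by 0.62 in wild type (limma adjusted p 0.0329) and by 0.63 in crhRTR.

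By rank, no opposite movement of antisense RNAs and the genes they lie against was found in wild type in the cold. Across 270 pairs, which are not independent replicates, Spearman's rho was −0.0425 (two-sided permutation p 0.49, adjusted p 0.54 over the 10 relations tested). The value of r was −0.224 and was not tested. Of 30 pairs with both members called, 16 went in opposite directions. In crhRTR rho was −0.152 (permutation p 0.013, adjusted p 0.021). Internal transcripts and the genes they lie in gave a rho of 0.841 across 147 pairs in wild type (permutation p 1e-05, the smallest the permutations can give, adjusted p 2e-05). The probes of such a pair share sequence and bind the same RNA, so this value decides nothing about separate transcripts.

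With 10 splits of 6 arrays the splits are too few for a share under 0.05. The real split gave 2158 features for the cold in wild type and the highest other 2, for the cold in crhRTR 2157 and 0, between strains at 30 °C 1099 and 2, and at 20 °C 1417 and 1. In each of these comparisons 1 split, the real one, reached the real count. The lists in camera behaved otherwise: the real split gave 15 in wild type and the highest other 11, and 15 and 15 for crhRTR, 10 and 18 at 30 °C, and 7 and 13 at 20 °C. As many lists came from 1, 3, 6 and 6 of the 10 splits. For the difference of the cold responses 84 of 100 splits gave at least the 6 lists called, with 19 as the highest, so chance in the grouping is not excluded for that count. For the overlap of the cold responses 1 of 100 splits, the real one, gave 1455 shared features, against 2 at the highest of the others. Other splits of a strain called at most 2 features, so an overlap that involves such a split was bound to be near 0. The value of 2 came from the split that kept the wild-type groups and exchanged the crhRTR temperatures. There both cold responses were present with opposed directions. The count therefore says only that each strain had a cold response, not that the sharing exceeds chance.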
